A study of Arabidopsis thaliana with 9 samples.

How the data were processed

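Transcripts were counted in seedlings of the flowering plant Arabidopsis thaliana. Per the labels, 3 genotypes were sampled: wild type of the Col-0 accession (WT), the atrzf1 mutant, and pca31, which the design text calls a suppressor of atrzf1. Each genotype had 3 libraries, numbered 1 to 3 in the sample titles. The headings of the deposited count columns carry the numbers 1 and 2 but none for the third library of each genotype, whose number comes from the title alone. The labels name no stress treatment for these samples, and they do not say whether the libraries of a genotype came from separate plant cultures. The p-values therefore measure only the spread between these samples, which may be technical.

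Per the labels' protocols, seedlings were 2 weeks old and grown on MS medium, RNA was extracted with TRIzol, and 500 ng of total RNA went into a Lexogen QuantSeq library. QuantSeq reads come from the 3' end of a transcript, so a count reflects transcripts without a correction for gene length. Per the submitters' processing notes, Bowtie2 and bedtools were used with the TAIR10 genome. Their versions, the strand setting, the annotation and any read filter are not given in the sources used here. The deposited values are raw counts per gene, as shown by whole numbers with a different total in each library. Each library lists 33323 gene identifiers, of which 0 are chloroplast or mitochondrial genes and 0 name no gene. Of these identifiers 32835 matched a locus tag of the RefSeq annotation of TAIR10.1, from which symbols, coordinates and strands were taken. Because the strand of counting is unknown, overlapping genes on opposite strands cannot be told apart in these counts. Near-identical copies, such as members of the LHCB1, LHCB2 and RBCS families and the pair PIP2;2 and PIP2;3, may have exchanged reads.

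The total count per library ran from 22478803 to 33073605, and 21417 to 22836 genes had at least 1 count. A floor of 3 counts, the largest true count that a count of 0 allows, corresponded to 0.0867 to 0.131 counts scaled by library size (CPM). The reads carry no molecular identifiers that the labels mention, so PCR copies are not independent molecules and these floors cover counting error only. Libraries of a genotype differed far beyond counting noise, with a smallest chi-square per degree of freedom of 191, so none was treated as a duplicate.

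Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 20672 genes, and libraries were scaled by TMM factors of 0.819 to 1.25. The quasi-likelihood test (glmQLFit and glmQLFTest) was fitted to all 9 libraries with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The contrasts were atrzf1 against WT, pca31 against atrzf1 and pca31 against WT, with an F test for any difference among the genotypes. CPM values use the TMM-scaled library size, and errors beside CPM are standard deviations over 3 libraries, while errors beside log2 fold changes are standard errors of the fit. A group with 0 counts in all of its libraries was set to 3 counts per library to give a lower bound of a fold.

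Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data. The Benjamini-Hochberg adjustment ran over the lists of a contrast, and a list needed 5 tested members. The 28 lists, the contrasts, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The lists were the rhamnogalacturonan lyase family, proline metabolism and transport, rhamnogalacturonan-I and rhamnose synthesis, homogalacturonan synthesis, pectin modification and degradation, expansins and xyloglucan endotransglucosylases, cellulose synthesis, dehydration and abscisic acid response, drought-related RING and U-box ubiquitin ligases, aquaporins, rapid touch, wound and cold responsive regulators, jasmonate and ethylene defence, salicylic acid defence, flavonoid and anthocyanin synthesis, aliphatic glucosinolate synthesis, heat shock proteins and factors, hypoxia response, iron deficiency, phosphate starvation, auxin response, senescence and sugar starvation, photosynthetic light harvesting and Rubisco small subunits, morning-expressed and afternoon- and evening-expressed clock genes, root markers, seed storage and oil body markers, floral identity and flowering-time markers, and reference genes. The rhamnogalacturonan lyase family (4 tested members) and the seed storage list (1) were too small for the list test, which left 26 lists.

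The rule for named genes took AtRZF1, the rhamnogalacturonan lyase family and the proline list in every group. Per contrast it took up to 10 called genes with the largest rise and 10 with the largest fall, provided that the higher group reached a mean of 5 CPM and the groups did not overlap. From each list it took up to 4 called members, or otherwise at most 2 members with the smallest p, given as values. Up to 10 genes called in opposite directions, and 10 called in the same direction in both mutants, completed it. Genes outside this rule are named too, and only some of them are marked as such. They include genes called under the replicate block and list members called adjusted over the list alone or by another fit. Further members of the floral and root lists are also among them.

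Samples with the same replicate number deviated together. Over all tested genes, deviations from the genotype means had correlations of 0.59 to 0.85 between libraries of the same number and of -0.74 to 0.27 between libraries of different numbers, and 9 of 9 libraries correlated best with a library of their own number. The first principal component, with 61.3% of the variance, parted the number 3 libraries from the rest. The numbers were therefore taken to pair the samples, and the fit with the replicate number as a block is given wherever it changes a call or moves a count by more than 1.5 times. The block lowered the common dispersion from 0.334 to 0.0562 and the residual degrees of freedom from 6 to 4.

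The procedure was tested on simulated counts for atrzf1 against WT with 20672 genes. Without the block, 0 of 100 genes changed 2-fold and 0 of 100 changed 4-fold were recovered. With the block, 43 of 100 and 84 of 100 were recovered, with 11 calls among 20414 unchanged genes. For gene lists, 3 of 3 shifted lists were called in both fits and 1 of 23 unshifted lists was called in both. With an estimated correlation 0 of 3 shifted lists were called without the block and 2 of 3 with it. In the real libraries that correlation was 0.326 for floral, 0.421 for jasmonate, 0.471 for light-harvesting and 0.669 for touch genes. It was 0.103 for aquaporins, 0.0238 for reference and -0.029 for homogalacturonan genes. Unblocked splits mixing genotypes called up to 12 lists in atrzf1 against WT, 14 in pca31 against atrzf1 and 11 in pca31 against WT. The 1 of 23 therefore does not give the rate of false calls among the real lists.

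Alternatives were DESeq2 1.42.0, limma-voom, the replicate block, median-of-ratios size factors, library totals, no filter beyond 1 count, a filter of 5 CPM in 3 libraries, the 6 libraries of a contrast alone, nuclear genes alone, an added 2-fold minimum with adjusted or unadjusted p, and leaving out each of the 9 libraries. The block combined with DESeq2 or limma-voom and the restriction to a pair of replicate numbers were added after the data were seen. For contrasts that share libraries, 20 sets of unchanged groups were simulated. Sequence copies of AT4G21620 were searched in TAIR10.1 with BLAST+ 2.17.0. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.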

Results

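Polyadenylated transcripts of Arabidopsis seedlings were counted by 3' end sequencing in 3 genotypes with 3 libraries each. WT was the Col-0 accession, atrzf1 a mutant of the RING-type E3 ubiquitin ligase gene AtRZF1, and pca31 a line that the series describes as suppressing atrzf1. The series concerns the dehydration response, proline synthesis and the pectin rhamnogalacturonan-I, and it names rhamnogalacturonan lyase 1 (RGL1), an enzyme class that cuts this pectin backbone, as the suppressor. Libraries numbered 1, 2 and 3 held 30842970, 29095181 and 22478803 counts in WT, 31120895, 27712644 and 23414231 in atrzf1, and 31556308, 33073605 and 24090783 in pca31. The 10 most abundant genes took 9.11% to 15.2% of the counts of a library.

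Libraries resembled each other by replicate number more than by genotype. Spearman correlations across genes were 0.965 to 0.982 between libraries of the same number and 0.855 to 0.963 between libraries of the same genotype. Library 2 of pca31 stood apart from the other number 2 libraries, at -3.7 on the second principal component against -65.7 in WT and -64.4 in atrzf1, with a TMM scaling factor of 1.047 against 0.819 and 0.8238. Root marker transcripts stood apart in the number 3 libraries, where their summed level was 2724 CPM in WT, 1844 in atrzf1 and 2403 in pca31, against 252 to 390 CPM in the 6 others. PHT1;1, a phosphate transporter of roots, was at 51.5 to 79.3 CPM in the number 3 libraries and at 0 to 0.178 CPM in the rest. PYK10, an abundant root beta-glucosidase, was at 1340 to 1850 CPM in number 3 and at 17.3 to 153 CPM in numbers 1 and 2. Light-harvesting and Rubisco small subunit transcripts took 14.1%, 9.03% and 6.77% of counts in WT libraries 1, 2 and 3, 13.7%, 8.56% and 6.52% in atrzf1, and 13.3%, 7.07% and 5.66% in pca31. Summed floral identity transcripts were 9.67 to 13.8 CPM in WT, 69.7, 39.0 and 19.9 CPM in atrzf1 libraries 1, 2 and 3, and 54.3, 64.7 and 18.4 CPM in pca31.

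**Figure D1:**
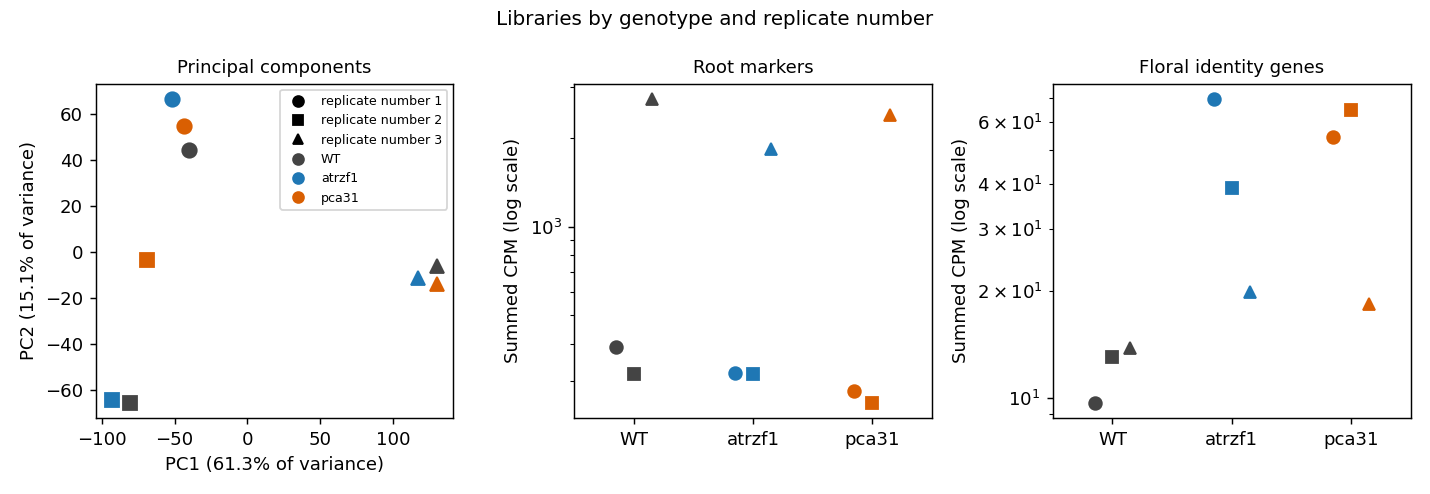
Principal components of the 9 libraries (percent of variance on each axis), summed root marker CPM and summed floral identity CPM (log axes), with genotype by colour and replicate number by symbol. The number 3 libraries lie at 117 to 130.3 on the first component and the others at -92.9 to -39.8, and root markers are at 1844 CPM or more in number 3 and at 390 CPM or less elsewhere.

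AtRZF1 (AT3G56580, TAIR10.1 chromosome 3, 20961543 to 20963817, plus strand) checks the genotype labels. Its level was 26.8 ± 3.68 CPM (SD, n = 3) in WT, 3 ± 1.39 CPM in atrzf1 and 2.29 ± 1.03 CPM in pca31. The 6 mutant libraries ranged from 1.16 to 4.6 CPM and the WT libraries from 24 to 31 CPM, so the low transcript level of atrzf1 was also present in pca31. The log2 fold change was -3.16 ± 0.46 (8.93-fold lower) in atrzf1 and -3.55 ± 0.46 (11.7-fold lower) in pca31, each against WT, with 3 of 3 libraries lower in both. The edgeR quasi-likelihood test without a block gave Benjamini-Hochberg adjusted p = 1 and 0.339 for these contrasts. With the replicate block they were -3.23 ± 0.27 and -3.62 ± 0.27, with edgeR adjusted p = 0.00113 and 0.000194. DESeq2 also called the gene in atrzf1 (adjusted p = 4.42e-07). Over all alternatives its adjusted p by edgeR, DESeq2 or limma-voom ran from 8.34e-25 to 1 in atrzf1 and from 2.58e-32 to 1 in pca31, with log2 fold changes of -3.60 to -2.96 and -3.88 to -3.23. Between pca31 and atrzf1 the change was -0.39 ± 0.43, within the spread between replicates.

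**Figure D2:**
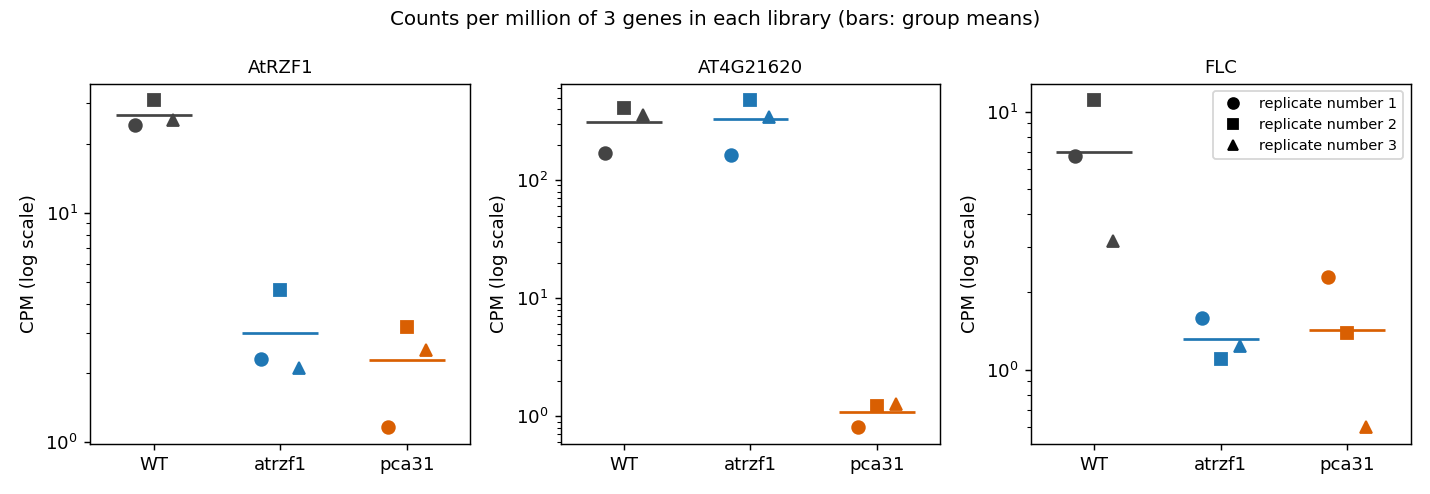
CPM (log axis) of AtRZF1, AT4G21620 and FLC in each library, with bars at group means and replicate number by symbol. AtRZF1 is at 24 to 31 CPM in WT and at 1.16 to 4.6 CPM in both mutants, AT4G21620 is at 0.805 to 1.26 CPM in pca31, and FLC is at 3.15 to 11.1 CPM in WT and 0.598 to 2.29 CPM in the mutants.

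The rhamnogalacturonan lyase family was near or below the limit of detection in most members, and the labels do not say which member is RGL1. AT1G09910 had the highest level, with 14.1 ± 4.88 CPM in WT, 12.2 ± 4.08 in atrzf1 and 11.8 ± 1.52 in pca31. Its log2 fold changes were -0.21 ± 0.34 in atrzf1 and -0.27 ± 0.34 in pca31 against WT, and -0.06 between the mutants. AT2G22620 averaged 0.686, 1.26 and 0.761 CPM in WT, atrzf1 and pca31, AT4G24430 averaged 0.356, 0.132 and 0.286 CPM, and AT1G09890 averaged 0.319, 0.171 and 0.277 CPM. AT2G22620 differed by 0.88 ± 0.56 on the log2 scale in atrzf1 against WT and by -0.73 ± 0.55 in pca31 against atrzf1. AT1G09880, AT4G37950 and AT4G38030 averaged at most 0.288 CPM in any genotype and were not tested. By edgeR's quasi-likelihood test 0 members were called in any contrast, with or without the block, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0.

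Proline metabolism and transport were measured in 10 genes. By edgeR's quasi-likelihood test 0 of them passed over all genes in any contrast, with 0 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. P5CS1, the main stress-induced enzyme of proline synthesis, was at 208 ± 100 CPM in WT, 153 ± 80.1 in atrzf1 and 177 ± 66.6 in pca31, with log2 differences of -0.44 ± 0.53, 0.21 ± 0.53 and -0.23 ± 0.53 for atrzf1 against WT, pca31 against atrzf1 and pca31 against WT. PRODH1, a proline dehydrogenase that starts proline breakdown, was at 32.7 ± 12.5, 38.2 ± 9.78 and 22.8 ± 6.86 CPM. Its level in pca31 lay below that in atrzf1 under all 3 replicate numbers, with a log2 fold change of -0.75 ± 0.37. Under the replicate block this was -0.79 ± 0.23 and passed when adjusted over the list alone (edgeR, adjusted p = 0.0458) but not over all genes (adjusted p = 0.956). In the order of those contrasts, log2 differences were -0.17, 0.08 and -0.09 for P5CS2, 0.04, -0.30 and -0.26 for P5CR, and 0.42, -0.35 and 0.06 for PRODH2. They were -0.11, 0.13 and 0.02 for the proline catabolic dehydrogenase P5CDH and -0.11, 0.17 and 0.06 for the ornithine aminotransferase OAT. The proline transporters PROT1 (-0.09, -0.07 and -0.17), PROT2 (0.23, -0.18 and 0.05) and PROT3 (-0.18, 0.08 and -0.10) completed the list. The proline list as a whole was not called by limma camera, with medians of -0.10, 0.00 and -0.10 and adjusted p = 1, 0.259 and 0.242. In atrzf1 against WT its test ran upward although its median and mean lay below 0, and with library totals the pca31 medians were 0.13 and 0.07. Without the block 0 members passed when adjusted over the list alone.

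The comparison of atrzf1 with WT asks which transcripts differ between the seedlings of these genotypes. For all genes named below in this paragraph, more floral tissue in some samples cannot be told apart from a dependence on AtRZF1. GRP16, CYP96A15, GRP14, EXL4 and XTH3 lay higher in atrzf1 libraries 1 and 2 and had 0 counts in every number 3 library. GRP16, an oleosin-type protein of the pollen coat, was at 11.9, 4.21 and 0 CPM in atrzf1 libraries 1, 2 and 3 and at 0 counts in WT, at least 46.1-fold higher against a floor of 3 counts per library. CYP96A15, a midchain alkane hydroxylase of wax synthesis, was at 54.6, 12.1 and 0 CPM in atrzf1 against 0.320, 0.504 and 0 CPM in WT. GRP14, another pollen coat glycine-rich protein, was at 2.91, 6.88 and 0 CPM against at most 0.178, and EXL4, an extracellular lipase of the pollen coat, was at 7.27, 5.08 and 0 CPM against at most 0.168. XTH3, a xyloglucan endotransglucosylase, was at 3.11, 4.07 and 0 CPM against 0 counts in WT, at least 20.5-fold higher. AT3G28500, a 60S acidic ribosomal protein gene, was at 130, 129 and 7 CPM against 27.9, 64.3 and 1.45 CPM.

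Without a block edgeR's quasi-likelihood test called 0 genes between atrzf1 and WT, with 115 genes at an unadjusted p under 0.05 against 1034 by chance. DESeq2 called 4 genes and limma-voom 0. The DESeq2 calls were AtRZF1 and AT3G01270, AT5G45880 and RALFL8, the last 3 of which were chosen for naming after their values were seen. AT3G01270, a pectate lyase gene, AT5G45880, a pollen allergen family gene, and RALFL8, a RALF-like peptide gene, were at 4.33, 7.30 and 5.31 CPM in atrzf1 library 1 and at 0 counts in atrzf1 libraries 2 and 3 and in WT. The replicate block gave 7 called genes, 6 higher and 1 lower, with 771 at an unadjusted p under 0.05. These were AtRZF1, GRP16 (edgeR, adjusted p = 0.0165) and, at adjusted p = 0.0355 each, GRP14, CYP96A15, XTH3, EXL4 and AT3G28500. Blocked log2 fold changes were 4.65 for GRP14, 6.20 for CYP96A15, 6.19 for EXL4 and 1.79 ± 0.25 for AT3G28500 (3.45-fold). All 3 atrzf1 libraries exceeded WT of the same number for AT3G28500, and 2 of 3 did for the 5 other higher genes. On simulated counts the fit without a block recovered 0 of 100 genes changed 4-fold, and the blocked fit 84 of 100.

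Floral identity genes rose in atrzf1 by the list test. The list had a median log2 fold change of 1.54, with 11 of 12 members above 0 (limma camera, adjusted p = 7.28e-05; adjusted p = 0.576 with an estimated correlation). PI and AP3, which specify petals and stamens, were at 10.2 ± 8.13 CPM against 2.07 ± 0.425 (2.3 ± 0.73 on the log2 scale) and at 2.81 ± 3.01 against 0.344 ± 0.389. SEP3, a cofactor of the floral organ regulators, was at 14.7 ± 7.99 CPM against 4.54 ± 3.98 (1.69 ± 0.63), and AP1, a floral meristem regulator, was at 3.82, 3.86 and 0.255 CPM against 0.284, 0.798 and 0. FLC, a repressor of flowering, was the member that went the other way, at 1.59, 1.1 and 1.24 CPM in atrzf1 against 6.72, 11.1 and 3.15 CPM in WT. FLC fell by 2.41 on the log2 scale (± 0.60), the 1 member called when adjusted over the list alone (edgeR, adjusted p = 0.037). Over all genes edgeR called 0 members with or without the block, with FLC, PI and SEP3 at an unadjusted p under 0.05 without it, and DESeq2 and limma-voom without a block called 0. Of the fits chosen after the data were seen, DESeq2 with the replicate block called FLC, AP1, SEP3, AP3 and PI over all genes (adjusted p = 0.00081, 0.00248, 0.00632, 0.00821 and 0.0203). The blocked edgeR fit to numbers 1 and 2 called SEP3 and PI (adjusted p = 0.0209 and 0.0272). Under the replicate block 7 members were called adjusted over the list alone, AP1, AP3, PI, SEP2, SEP3 and FUL higher and FLC lower. Within replicate numbers 1, 2 and 3 the list's median was 2.57, 1.4 and 0.53. The list call was lost without atrzf1 library 1 (limma camera, adjusted p = 0.0852), the highest of 9.69e-07 to 0.0852 over single libraries left out. The floral list call held under the other scalings, no filter and the replicate block (limma camera, adjusted p = 1.42e-05 to 0.000644), while the 5 CPM filter left too few members to test. It also held in 4 of 4 fits to a pair of replicate numbers, which were chosen after the data were seen (7.36e-10 to 0.0202).

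Rapid touch, wound and cold responsive regulators rose in atrzf1 by the list test, with 14 of 18 above 0 and a median of 0.23 (limma camera, adjusted p = 0.00467; adjusted p = 0.991 with an estimated correlation). Examples are TCH2, a calmodulin-like touch gene (126 ± 32.8 CPM against 86.8 ± 33.1, 0.53 ± 0.44), and ZAT12, a zinc finger stress regulator (7.76 ± 1.21 against 4.91 ± 2.44, 0.66 ± 0.60). Its medians within numbers 1, 2 and 3 were -0.20, 0.82 and 0.75. The call was lost without WT library 2 (limma camera, adjusted p = 0.57, median -0.08), WT library 3 (0.408) or atrzf1 library 1 (0.27), in a range of 4.61e-10 to 0.57 over libraries left out. It held in 1 of the 4 fits to a pair of replicate numbers (3.41e-05 to 0.347). Jasmonate and ethylene defence genes fell by the list test, with 20 of 24 below 0 and a median of -0.35 (limma camera, adjusted p = 0.0242; adjusted p = 0.991 with an estimated correlation). AOC1, an allene oxide cyclase of jasmonate synthesis, was at 15.8 ± 3.06 CPM against 46.5 ± 20.1 (-1.56 ± 0.55), and ORA59, an ethylene response factor, at 7.22 ± 6.60 against 13.9 ± 9.90 (-0.95 ± 0.78). Within numbers 1, 2 and 3 the jasmonate medians were -0.18, -0.61 and -0.64. That call was lost with no filter (limma camera, adjusted p = 0.0605) and without WT library 1 (0.0741), WT library 2 (0.86, direction reversed), atrzf1 library 1 (0.258) or atrzf1 library 3 (0.824), in a range of 0.000114 to 0.86, and held in 3 of the 4 fits to a pair of numbers (0.00518 to 0.129). In both lists 0 members were called adjusted over the list alone.

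Root markers had 16 of 18 members below 0 in atrzf1, with a median of -0.56, and were not called without the block (limma camera, adjusted p = 0.664). Under the replicate block they fell (limma camera, adjusted p = 0.0098; adjusted p = 0.776 with an estimated correlation). Their medians within numbers 1, 2 and 3 were 0.0, 0.0 and -0.60, and PYK10, CASP1, BGLU21 and BGLU22 were called lower adjusted over the list alone. DESeq2 with the replicate block, chosen after the data were seen, called PYK10 lower over all genes (adjusted p = 0.000409). CASP1, a protein of the root endodermal barrier, was at 3.21, 4.64 and 28.3 CPM in atrzf1 and at 4.83, 5.79 and 53.4 CPM in WT. The heat shock list was not called (limma camera, adjusted p = 0.441, median -0.20), but with the block HSP70-4 (-0.77 ± 0.18) and HSP90.1 (-0.57 ± 0.17), both heat-inducible chaperones, were called lower adjusted over the list alone.

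Other lists were not called between atrzf1 and WT by limma camera, with 0 members called adjusted over the list alone, and the adjusted p and median of each follow. For pectin and the cell wall these were 0.833 and 0.01 for rhamnogalacturonan-I and rhamnose synthesis, 0.171 and 0.19 for homogalacturonan synthesis, 0.636 and 0.05 for pectin modification and degradation, 0.648 and 0.06 for expansins and xyloglucan endotransglucosylases, and 0.664 and -0.04 for cellulose synthesis. Here RHM3, a rhamnose synthase, differed by 0.38 ± 0.27 on the log2 scale and PMEI13, a pectin methylesterase inhibitor, by 0.48 ± 0.34. The dehydration and abscisic acid list gave 0.454 and -0.04. The abscisic acid responsive dehydrin RAB18 was at 115, 52.6 and 812 CPM in WT and at 120, 82.3 and 132 CPM in atrzf1, with a log2 difference of -1.55 ± 0.85. Drought-related ubiquitin ligases gave 0.993 and -0.05, aquaporins 0.601 and -0.09, and salicylic acid defence 0.904 and -0.15. Flavonoid synthesis gave 0.833 and -0.15, aliphatic glucosinolate synthesis 0.775 and -0.01, hypoxia response 0.0842 and 0.42, iron deficiency 0.648 and -0.02, and phosphate starvation 0.833 and -0.06. Auxin response gave 0.742 and -0.08, senescence and sugar starvation 0.648 and 0.17, light harvesting and Rubisco 0.699 and -0.13, and reference genes 0.6 and -0.09. Morning and evening clock genes gave 0.699 and -0.07, and 0.648 and 0.12. The mean differed in sign from the median for rhamnogalacturonan-I synthesis (-0.02), iron deficiency (0.17) and phosphate starvation (0.06). Hypoxia response passed only with library totals (limma camera, adjusted p = 0.0233) and homogalacturonan synthesis only with the 5 CPM filter (0.0426), apart from fits with libraries left out. In the fit to numbers 1 and 3 hypoxia, homogalacturonan, senescence and evening clock genes rose and iron deficiency, heat shock and root genes fell (limma camera, adjusted p = 0.00345 to 0.0449), and root genes fell also with numbers 2 and 3 (0.0202). Without WT library 2 hypoxia genes rose and heat shock, auxin and morning clock genes fell (limma camera, adjusted p = 0.00109 to 0.0397). Without WT library 3 root and phosphate genes rose and salicylic acid, iron and light-harvesting genes fell (0.0118 to 0.0319). Without atrzf1 library 3 root, phosphate and heat shock genes fell (limma camera, adjusted p = 0.00268 to 0.025), without atrzf1 library 2 iron and flavonoid genes did (0.0251 and 0.0254), and hypoxia genes rose without atrzf1 library 1 (0.0496) or pca31 library 3 (0.028). Only OLEO1, an oil body protein, was testable among seed storage genes, with differences of 0.01, 0.08 and 0.09 in the 3 contrasts.

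**Figure D3:**
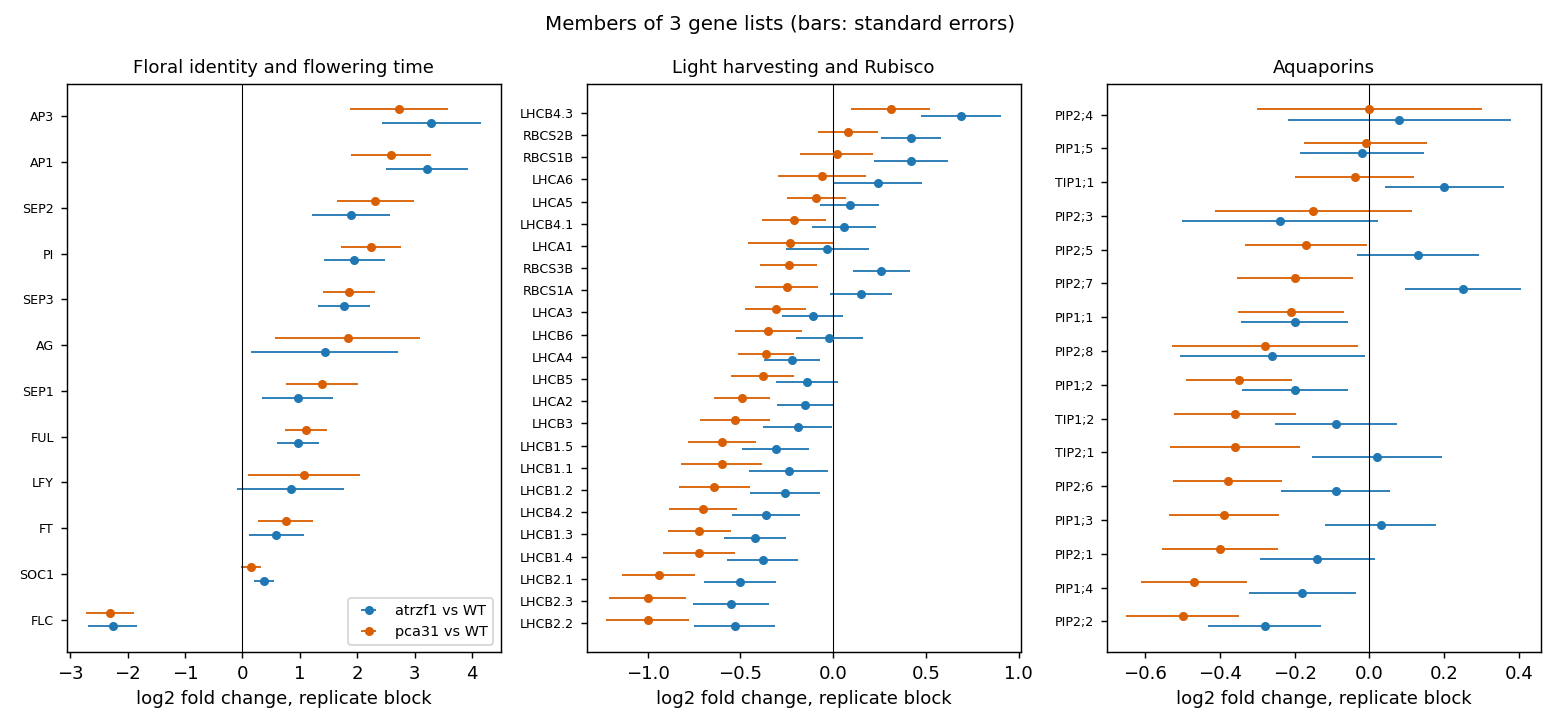
Log2 fold changes against WT from the blocked fit for the members of 3 lists in atrzf1 and pca31, with standard errors as bars. FLC is the floral member far below 0 in both mutants (-2.26 and -2.30), and 21 of 24 light-harvesting and Rubisco genes and 15 of 16 aquaporins have unblocked fold changes below 0 in pca31.

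The comparison of pca31 with atrzf1 asks what the suppressor changes in the atrzf1 background, and 1 gene stood out. AT4G21620, annotated as a glycine-rich protein gene (TAIR10.1 chromosome 4, 11491264 to 11492216, plus strand), was at 328 ± 157 CPM in atrzf1, 311 ± 127 CPM in WT and 1.09 ± 0.251 CPM in pca31. The 3 pca31 libraries held 25, 42 and 38 counts of it. Its log2 fold change was -8.22 ± 0.63 (299-fold lower), with 3 of 3 libraries lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00785). The 20 nearest tested genes, from 11450552 to 11546716, had fold changes of -0.72 to 1.23 on the log2 scale. The nearest neighbours with a mean of 1 CPM or more, AT4G21610 and AT4G21650, differed by 0.04 and 0.05. AT4G21640, which lies nearer (11496834 to 11500618), averaged 0.222, 0.258 and 0.509 CPM in WT, atrzf1 and pca31 (0.98 ± 1.16). Part of the AT4G21620 sequence has a copy of 92.3% identity over 104 bases in AT4G21650 and one of 84.4% over 366 bases at 11496441 to 11496800, where no gene is annotated.

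AT4G21620 was the 1 gene that edgeR's quasi-likelihood test called between pca31 and atrzf1, with 44 genes at an unadjusted p under 0.05. The same number, 1, was called by DESeq2, limma-voom and the replicate block (914 at an unadjusted p under 0.05). The call was lost without pca31 library 1 (edgeR, adjusted p = 0.137), 2 (0.162) or 3 (0.112), each of which left 2 pca31 libraries, while the log2 fold change stayed between -8.55 and -7.85 over all alternatives. Over those alternatives the adjusted p of the edgeR, DESeq2 and limma-voom fits ran from 1.04e-277 to 0.58, the latter with numbers 1 and 2 alone and no block.

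**Figure D4:**
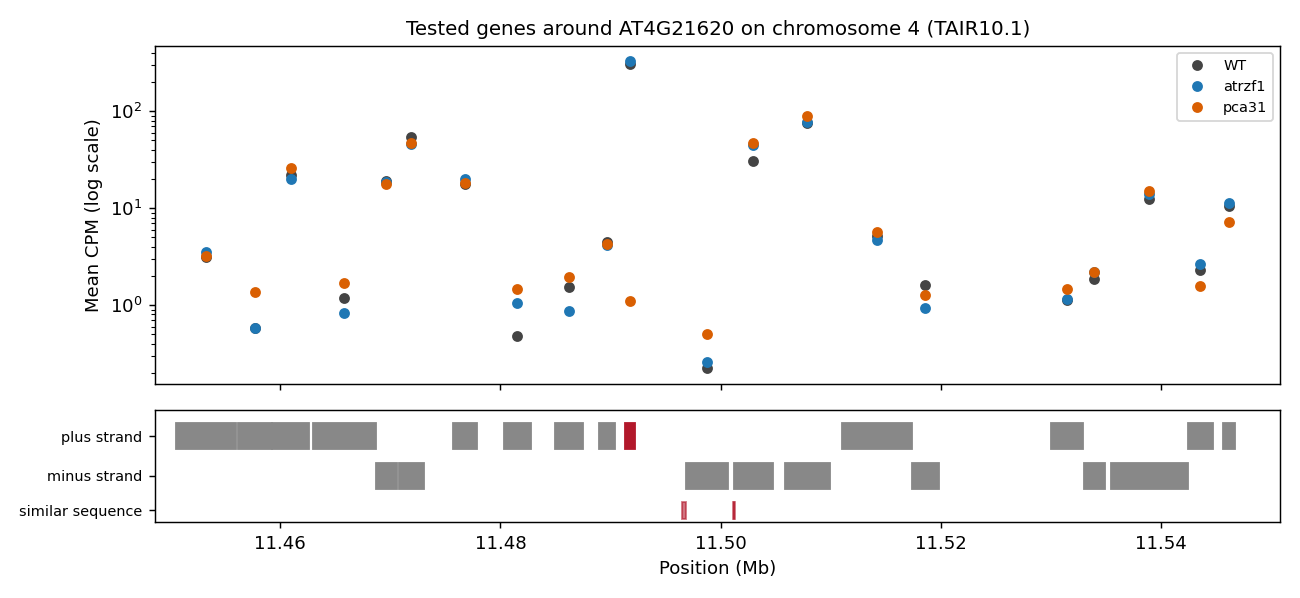
Mean CPM (log axis) of AT4G21620 and tested neighbours along chromosome 4 (TAIR10.1, Mb) in the 3 genotypes, above gene positions by strand and stretches similar to AT4G21620. AT4G21620 is at 328 CPM in atrzf1 and 1.09 CPM in pca31, and its neighbours differ by -0.72 to 1.23 on the log2 scale.

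Aquaporins fell from atrzf1 to pca31 as a list, with 15 of 16 members below 0 and a median of -0.27 (limma camera, adjusted p = 0.000482; adjusted p = 0.725 with an estimated correlation). PIP2;7 and PIP1;3, water channels of the plasma membrane, were at 439 ± 28.9 against 599 ± 43.1 CPM (-0.45 ± 0.24) and at 523 ± 74.5 against 698 ± 69.8 CPM (-0.42 ± 0.27). Aquaporin medians within numbers 1, 2 and 3 were -0.26, -0.52 and -0.02, the lowest in number 2, where the pca31 library stood apart. The call held in 3 of the 4 fits to a pair of numbers (limma camera, adjusted p = 0.000165 to 0.156) and was lost without atrzf1 library 2 (limma camera, adjusted p = 0.0868, range 0.000431 to 0.0868). Light-harvesting and Rubisco small subunit genes fell too by the list test, with 24 of 24 below 0 and a median of -0.27 (limma camera, adjusted p = 0.00234; adjusted p = 0.95 with an estimated correlation). RBCS3B, a Rubisco small subunit, was at 7210 ± 2730 against 10300 ± 4350 CPM (-0.51 ± 0.50), and LHCA2, an antenna protein of photosystem I, at 2770 ± 1130 against 3490 ± 1300 CPM (-0.34 ± 0.47). Photosynthesis medians were -0.13, -0.60 and -0.31 within numbers 1, 2 and 3, again lowest in number 2. The photosynthesis call held in 4 of 4 fits to a pair of numbers (limma camera, adjusted p = 1.54e-09 to 0.0147). It was lost without atrzf1 library 1 (limma camera, adjusted p = 0.684, median 0.12), pca31 library 2 (0.112) or pca31 library 3 (0.634), in a range of 1.34e-11 to 0.684. With library totals the aquaporin and photosynthesis medians were -0.11 and -0.14, or -0.26 and -0.29 relative to all genes. Both lists were still called there (limma camera, adjusted p = 0.0104 and 5e-05). In both lists 0 members were called adjusted over the list alone.

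Heat shock proteins and factors had 14 of 16 members above 0 in pca31 against atrzf1 and a median of 0.28, not called without the block (limma camera, adjusted p = 0.0874). In the fit with the replicate block they rose (limma camera, adjusted p = 0.0371; adjusted p = 0.935 with an estimated correlation), with medians of 0.37, 0.80 and -0.06 within numbers 1, 2 and 3, the highest in number 2, where pca31 library 2 stood apart. They rose also with no filter (limma camera, adjusted p = 0.0195), without pca31 library 2 (0.0104) or atrzf1 library 3 (0.000411), and in both fits to numbers 1 and 2 (0.0114 with the block and 0.00869 without). HSFA7A, a heat shock factor, differed by 0.71 ± 0.83, and HSP101, a chaperone, by 0.26 ± 0.45. Root markers had a median of 0.60 with 15 of 18 above 0 while the unblocked test ran downward (limma camera, adjusted p = 0.86), and BGLU21 and BGLU22 were called higher with the block adjusted over the list alone.

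Other lists were not called between pca31 and atrzf1 by limma camera, and 0 of their members were called without the block adjusted over the list alone. Expansins and xyloglucan endotransglucosylases had 22 of 24 members below 0, with a median of -0.23 (limma camera, adjusted p = 0.0766). Rhamnogalacturonan-I synthesis, homogalacturonan synthesis and pectin modification had medians of -0.01, -0.01 and -0.08 (limma camera, adjusted p = 0.86, 0.843 and 0.86). ARAD2, an arabinosyltransferase gene of pectin side chains, differed by 1.28 ± 0.63, and PME5, a pectin methylesterase, by -0.40 ± 0.24. The dehydration and abscisic acid list had a median of 0.09 (limma camera, adjusted p = 0.86), with ANAC019, a stress-responsive NAC factor, at 23.1 ± 8.34 CPM against 13.5 ± 0.703 (0.78 ± 0.40). Drought-related ubiquitin ligases had a median of 0.22 (limma camera, adjusted p = 0.206), and the floral list one of 0.09 (0.86). Rapid touch and jasmonate lists had medians of 0.14 and 0.20 while their tests ran downward (limma camera, adjusted p = 0.86 each). The remaining lists had adjusted p from 0.259 to 0.86 by limma camera. Signs of median and mean differed for rhamnogalacturonan-I synthesis (mean 0.09), homogalacturonan synthesis (0.04) and pectin modification (0.05), and floral, flavonoid and iron lists were tested in the direction opposite to their medians (0.09, -0.02 and -0.11). With library totals expansins and salicylic acid defence passed downward (limma camera, adjusted p = 0.0243 and 0.034). Of the fits chosen after the data were seen, both with numbers 1 and 2 called senescence genes higher (limma camera, adjusted p = 0.0378 with the block and 0.0235 without). That with numbers 1 and 3 called touch, jasmonate, root and ubiquitin ligase genes higher and salicylic acid and morning clock genes lower (limma camera, adjusted p = 0.00322 to 0.0474). That with numbers 2 and 3 called root genes higher and expansins, salicylic acid and jasmonate genes lower (7.29e-05 to 0.0467), so jasmonate genes were called in both directions. Without atrzf1 library 2 flavonoid and iron genes rose and glucosinolate, phosphate, auxin and morning clock genes fell (limma camera, adjusted p = 0.0174 to 0.0438). Without pca31 library 1 salicylic acid, glucosinolate, touch and jasmonate genes fell (7.49e-06 to 0.00656), and without pca31 library 3 jasmonate and floral genes rose and expansins, phosphate and root genes fell (0.00259 to 0.027). Expansins fell also without atrzf1 library 1 (limma camera, adjusted p = 0.0267), senescence genes rose without atrzf1 library 3 (0.00111) and touch genes without pca31 library 2 (0.00049).

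The comparison of pca31 with WT shows what the suppressor line retains or adds. AT4G21620 was 283-fold lower, with a log2 fold change of -8.14 ± 0.62 and 3 of 3 libraries lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00829). GRP16 was at 18.4, 18.6 and 0 CPM in pca31 libraries 1, 2 and 3 (at least 106-fold higher than WT), CYP96A15 at 36.5, 58.8 and 0 CPM, and EXL4 at 8.47, 9.13 and 0 CPM. AT5G37940, a zinc-binding dehydrogenase gene, was at 47.4, 58.0 and 0 CPM against 0.498, 3.11 and 0 CPM. XTH3 was at 4.31, 6.19 and 0 CPM and GGPS2, a geranylgeranyl pyrophosphate synthase, at 4.47, 5.98 and 0 CPM, at least 30-fold and 29.8-fold higher than WT, which had 0 counts of both. GRP14 was at 6.25, 9.10 and 0 CPM. As in atrzf1, more floral tissue in some samples cannot be told apart from a genotype effect for all genes named here other than AT4G21620.

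Without a block edgeR's quasi-likelihood test called 1 gene, AT4G21620, between pca31 and WT, with 190 at an unadjusted p under 0.05. DESeq2 called 5 genes and limma-voom 1. The DESeq2 calls were AT4G21620, AtRZF1, AT3G01270, AT5G45880 and RALFL8. The replicate block gave 9 called genes, 7 higher and 2 lower, with 1745 at an unadjusted p under 0.05. The lower genes were AtRZF1 and AT4G21620. The higher genes, at edgeR adjusted p of 0.00263 to 0.0437, were GRP16, GRP14, CYP96A15, XTH3, EXL4, AT5G37940 and GGPS2. Each of these 7 exceeded WT of the same number in 2 of 3 pca31 libraries and was at 0 in pca31 library 3. The AT4G21620 call was lost without pca31 library 1 (edgeR, adjusted p = 0.144), 2 (0.169) or 3 (0.118), within 2.23e-274 to 0.29 over all alternatives and tools.

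Aquaporins fell as a list in pca31 against WT, with 15 of 16 below 0 and a median of -0.36 (limma camera, adjusted p = 6.05e-05; adjusted p = 0.43 with an estimated correlation). PIP1;4 was at 342 ± 39.4 CPM against 471 ± 6.25 (-0.46 ± 0.23), and PIP2;2, which may share reads with PIP2;3, at 58.3 ± 2.65 against 82.3 ± 6.57 (-0.50 ± 0.20). The aquaporin call held without each single library (limma camera, adjusted p = 5.44e-05 to 0.0101), and in 4 of 4 fits to a pair of numbers (0.000143 to 0.0149), with medians of -0.13, -0.45 and -0.35 within numbers 1, 2 and 3, the lowest in number 2, where pca31 library 2 stood apart. Light-harvesting and Rubisco genes fell as a list, with 21 of 24 below 0 and a median of -0.33 (limma camera, adjusted p = 0.0017; adjusted p = 0.797 with an estimated correlation). LHCA2 was at 2770 ± 1130 CPM against 3830 ± 1320 (-0.47 ± 0.47), and LHCB1.5, an antenna protein of photosystem II, at 9180 ± 5330 against 13200 ± 4740 (-0.52 ± 0.55). Adjusted over the list alone, 0 photosynthesis genes were called without the block and 11 with the replicate block, all lower, of LHCB1, LHCB2, LHCB3, LHCB4.2 and LHCA2, several of which are near-identical copies. With library totals the aquaporin and photosynthesis medians were -0.16 and -0.13, or -0.36 and -0.33 relative to all genes. Both lists were still called there (limma camera, adjusted p = 0.00136 and 3.98e-05). Photosynthesis medians within numbers 1, 2 and 3 were -0.20, -0.76 and -0.33, again lowest in number 2. DESeq2 with the replicate block, a fit chosen after the data were seen, called LHCB2.1, LHCB2.2, LHCB2.3, LHCB1.3, LHCB1.4 and LHCB4.2 lower over all genes (adjusted p = 0.000581 to 0.0276). The list call held in 4 of 4 fits to a pair of numbers (6.1e-09 to 0.00597 by limma camera) and was lost without WT library 1 (limma camera, adjusted p = 0.446), pca31 library 2 (0.0664) or pca31 library 3 (0.539), in a range of 3.58e-11 to 0.539.

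Floral identity genes rose in pca31 against WT by the list test, with 11 of 12 above 0 and a median of 1.78 (limma camera, adjusted p = 0.00346; adjusted p = 0.687 with an estimated correlation). PI was at 12.3 ± 7.81 CPM against 2.07 ± 0.425 (2.57 ± 0.73) and SEP3 at 14.0 ± 1.63 against 4.54 ± 3.98 (1.62 ± 0.63). FLC fell by 2.29 on the log2 scale (± 0.60), at 2.29, 1.39 and 0.598 CPM in pca31. Adjusted over the list alone FLC and PI were called by edgeR (adjusted p = 0.0404 each), and 7 members with the replicate block, the 6 higher and FLC lower named for atrzf1. Of the fits chosen after the data were seen, DESeq2 with the replicate block called FLC, PI and SEP3 over all genes (adjusted p = 0.000177, 0.00129 and 0.00197) and limma-voom with it PI and FLC (0.0372 each). The blocked edgeR fit to numbers 1 and 2 called PI and SEP3 (adjusted p = 0.00955 and 0.0105). The list medians were 2.3, 1.83 and 0.05 within numbers 1, 2 and 3, and the call was lost without WT library 3 (limma camera, adjusted p = 0.0938) or pca31 library 2 (0.179), in a range of 4.16e-07 to 0.179. It held in 4 of 4 fits to a pair of numbers (1.1e-07 to 0.019). SOC1, a floral integrator, was at 67.1, 72.9 and 54.7 CPM in pca31, 87.5, 67.9 and 73.4 in atrzf1 and 55.7, 52.1 and 67.1 in WT. FT, the mobile flowering signal, was at 0.676, 1.97 and 5.25 CPM in pca31, 0.609, 2.54 and 3.5 in atrzf1 and 0.746, 1.6 and 1.3 in WT.

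Rapid touch, wound and cold regulators rose as a list in pca31 against WT, with 16 of 18 above 0 and a median of 0.44 (limma camera, adjusted p = 0.0206; adjusted p = 0.797 with an estimated correlation). ZAT12 was at 9.87 ± 6.37 CPM against 4.91 ± 2.44 (1.00 ± 0.60) and WRKY40, a defence regulator, at 13.0 ± 4.71 against 7.84 ± 5.05 (0.73 ± 0.45). Medians were 0.16, -0.05 and 1.03 within numbers 1, 2 and 3. This call was lost with library totals (limma camera, adjusted p = 0.0757) and without WT library 2 (0.499), WT library 3 (0.487), pca31 library 1 (0.928) or pca31 library 3 (0.381), in a range of 1.87e-10 to 0.928, and held in 2 of the 4 fits to a pair of numbers (3.45e-05 to 0.965). Jasmonate and ethylene defence genes passed downward (limma camera, adjusted p = 0.0206; adjusted p = 0.797 with an estimated correlation), but 12 members lay above and 12 below 0, with a median of 0.00 and a mean of -0.20. AOC1 was at 44.6, 14.3 and 11.1 CPM in pca31 against 26.2, 46.9 and 66.4 CPM in WT. The jasmonate median was -0.05 with median-of-ratios factors and 0.13 with library totals, and within numbers 1, 2 and 3 it was 0.93, -1.13 and -0.61. That call was lost without WT library 2 (limma camera, adjusted p = 0.971, direction reversed), pca31 library 2 (0.179) or pca31 library 3 (0.984), in a range of 1.05e-10 to 0.984, and held in 1 of the 4 fits to a pair of numbers (1.38e-10 to 0.531). With all 9 libraries 0 members of both lists were called adjusted over the list alone by edgeR. The blocked edgeR fit to numbers 2 and 3, chosen after the data were seen, called AOC1, LOX2, VSP2 and AOC2 lower over all genes (adjusted p = 0.011, 0.024, 0.043 and 0.043).

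Reference genes fell as a list in pca31 against WT, with 7 of 8 below 0 and a median of -0.21 (limma camera, adjusted p = 0.0452; adjusted p = 0.43 with an estimated correlation). Their medians within numbers 1, 2 and 3 were -0.30, -0.48 and 0.11, the lowest in number 2. UBQ10, a polyubiquitin gene, was at 11800 ± 631 CPM against 17500 ± 4010 (-0.57 ± 0.30), and GAPC1, a glycolytic dehydrogenase, at 245 ± 45.7 against 342 ± 86.4 (-0.48 ± 0.32). Under the replicate block the call was lost (limma camera, adjusted p = 0.06). Scaling by library totals moved the median of all genes by 0.205 in this contrast and by 0.15 in pca31 against atrzf1. Under it the reference median was 0.01, or -0.19 relative to all genes, and the list was not called (limma camera, adjusted p = 0.0757). Leaving out any library but WT library 3 also ended this call, with adjusted p = 0.142 and 0.251 without WT libraries 1 and 2, 0.0509, 0.0501 and 0.0602 without atrzf1 libraries 1, 2 and 3, and 0.127, 0.0809 and 0.156 without pca31 libraries 1, 2 and 3 (limma camera, range 0.0245 to 0.251). It held in 2 of the 4 fits to a pair of numbers (0.0365 to 0.261). Homogalacturonan synthesis genes rose as a list, with 9 of 11 above 0 and a median of 0.17 (limma camera, adjusted p = 0.0481; adjusted p = 0.43 with an estimated correlation). GAUT13, a galacturonosyltransferase, was at 5.61 ± 1.46 CPM against 3.35 ± 0.882 (0.74 ± 0.38) and CGR3, a pectin methyltransferase, at 11 ± 2.23 against 8.33 ± 0.733 (0.40 ± 0.25). In the fit with the replicate block this call was lost too (limma camera, adjusted p = 0.0615), as with median-of-ratios factors (0.0516) and no filter (0.113). It was also lost without WT library 1 (limma camera, adjusted p = 0.0834) or 3 (0.408), atrzf1 library 1 (0.0652) or 3 (0.0705), or pca31 library 1 (0.167), 2 (0.179) or 3 (0.0669), in a range of 0.0388 to 0.408, and held in 1 of the 4 fits to a pair of numbers (0.0469 to 0.328). In both lists 0 members were called adjusted over the list alone.

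Other lists were not called between pca31 and WT by limma camera, and 0 of their members were called without the block adjusted over the list alone. Rhamnogalacturonan-I synthesis and pectin modification had medians of 0.03 and 0.04 (limma camera, adjusted p = 0.669 and 0.634), and the dehydration and abscisic acid list one of -0.11 (0.39), or 0.07 with library totals. ANAC019 differed by 0.98 ± 0.41 on the log2 scale. DESeq2 with the replicate block, chosen after the data were seen, called KIN2, a cold and abscisic acid responsive gene of that list, lower over all genes (-0.96, adjusted p = 0.0207), and PYK10 of the root list too (-0.85, adjusted p = 0.0164). Drought-related ubiquitin ligases and senescence genes had medians of 0.23 and 0.26 (limma camera, adjusted p = 0.198 each). DIN2, a dark-induced beta-glucosidase, differed by 1.96 ± 0.97. Salicylic acid defence had a median of -0.24 (limma camera, adjusted p = 0.198) and passed with library totals (0.0278), where its median was 0.00. PR5, a pathogenesis-related protein gene, differed by -1.65 ± 0.95. Flavonoid synthesis had a median of -0.15 (limma camera, adjusted p = 0.834), and with the replicate block FLS1 and MYB111, a flavonol synthase and its regulator, were called higher (0.95 ± 0.25 and 0.97 ± 0.23) and LDOX, an anthocyanidin synthase, lower (-1.09 ± 0.29) adjusted over the list alone. Root markers had a median of 0.04 (limma camera, adjusted p = 0.41) and passed downward with library totals (0.0418), where their median was 0.21, or 0.01 relative to all genes. Of these PYK10 was called lower with the block adjusted over the list alone (-0.82 ± 0.22). The remaining lists had adjusted p from 0.127 to 0.8 by limma camera. The root, iron and auxin lists were tested downward with medians of 0.04, 0.09 and 0.04. Of the fits chosen after the data were seen, that with numbers 1 and 3 called senescence, ubiquitin ligase and evening clock genes higher and morning clock genes lower (limma camera, adjusted p = 0.00406 to 0.0217). That with numbers 2 and 3 called salicylic acid, phosphate, glucosinolate, flavonoid and dehydration genes lower (0.00579 to 0.0311). Without pca31 library 1 salicylic acid, glucosinolate, morning clock and dehydration genes fell (limma camera, adjusted p = 6.51e-06 to 0.0457), and without WT library 2 glucosinolate, auxin and morning clock genes did (0.000716 to 0.0336). Phosphate genes fell without WT library 1 (limma camera, adjusted p = 0.0483), salicylic acid genes without WT library 3 (0.00129), and root and phosphate genes without pca31 library 3 (0.000913 and 0.00937), while senescence genes rose without pca31 library 2 (0.0237).

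The design text states the hypothesis that AtRZF1 and RGL1 act on a number of target genes in opposite ways, which asks for genes that moved one way in atrzf1 and back in pca31. By edgeR's quasi-likelihood test 0 genes were called in opposite directions in atrzf1 against WT and pca31 against atrzf1, and the count was 0 with DESeq2, limma-voom and the replicate block. EdgeR without the block and limma-voom could only give 0, as they called 0 genes in atrzf1 against WT. DESeq2 and the replicate block could give at most 1, the number called in pca31 against atrzf1. These counts therefore do not answer whether such genes exist. With an unadjusted p under 0.05 and a 2-fold change, 4 genes were called in opposite directions. No number was simulated at this threshold, and the shared atrzf1 libraries alone can give opposite signs. From atrzf1 to pca31 AtRZF1 differed by -0.39 ± 0.43, FLC by 0.12 ± 0.58 and the floral list by a median of 0.09, or -0.35, 0.60 and -0.07 within numbers 1, 2 and 3. AT4G21620 differed by 0.08 ± 0.45 between atrzf1 and WT. Fold changes of the 2 contrasts correlated at -0.24 across genes, against -0.51 for simulated unchanged groups sharing the atrzf1 libraries, with covariances of -0.06 and -0.11. Opposite signs were seen in 59.7% of genes against 66.9% in simulation.

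In both mutants against WT, edgeR's quasi-likelihood test called 0 genes in the same direction without the block, limma-voom 0 and DESeq2 4. An unadjusted p under 0.05 with a 2-fold change gave 50 genes, and no number was simulated at this threshold. The replicate block gave 6, namely GRP16, GRP14, CYP96A15, XTH3 and EXL4 higher and AtRZF1 lower. Simulated unchanged groups sharing the WT libraries gave a mean of 0.25 and at most 1 in 20 simulations. Independent lists of these sizes would share 0.002 higher and 9.7e-05 lower genes, but lists that share the WT libraries are not independent. The low AtRZF1 level is moreover a trait of both mutant lines. The simulation held no tissue differences between libraries of the same number. Neither number therefore measures how far the 6 genes exceed chance. Fold changes correlated at 0.78 across genes against 0.51 in simulation, with a covariance of 0.28 against 0.11, and 68.5% against 66.7% of genes had the same sign. Genes are not independent replicates, and part of the excess may come from the shared WT libraries, which at 3 cannot be split into parts of 2. Over all 3 genotypes the edgeR F test called 1 gene, AT4G21620 (adjusted p = 0.0258), with 55 at an unadjusted p under 0.05. DESeq2 called 3, limma-voom 1 and edgeR with the replicate block 8 (1159 at an unadjusted p under 0.05). The single call was lost without WT library 2 or 3, atrzf1 library 2 or 3, or any pca31 library, each leaving 0 genes.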

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

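The fits named as added were chosen after the data were seen, and the other alternatives were fixed before the data were examined. Counts of genes below are in the order atrzf1 against WT, pca31 against atrzf1, pca31 against WT, all 3 genotypes, and both mutants against WT in the same direction. Without a block edgeR called 0, 1, 1, 1 and 0. The counts were the same with median-of-ratios factors, library totals, no filter beyond 1 count, a filter of 5 CPM in 3 libraries, limma-voom, and an added 2-fold minimum, and for the first 3 with only the libraries of the contrast. Leaving out organelle genes was void, since the files hold 0 of them. DESeq2 called 4, 1, 5, 3 and 4, and edgeR with the replicate block 7, 1, 9, 8 and 6. An unadjusted p under 0.05 with a 2-fold change gave 87, 23, 112, 41 and 50, and 4 genes in opposite directions, a count that was 0 under every other setting. Leaving out 1 library gave 0, 0 to 1, 0 to 1, 0 to 1 and 0, and 0 in opposite directions. The pca31 calls ended without any 1 pca31 library and the call among all genotypes also without WT library 2 or 3 or atrzf1 library 2 or 3. The cause of these losses was not tested.

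Of the added fits, DESeq2 with the replicate block called 47, 2, 116, 67 and 34 genes and limma-voom with the replicate block 5, 2, 22, 14 and 5. The fit to numbers 1 and 2 with the replicate block called 16, 1, 28, 18 and 16, that to numbers 1 and 3 called 7, 1, 10, 9 and 7, and that to numbers 2 and 3 called 3, 1, 18, 9 and 3. Numbers 1 and 2 with no block gave 0 in each. In pca31 against WT the blocked fits called 46 genes higher and 70 lower with DESeq2, and 13 and 9 with limma-voom. For numbers 1 and 2, 1 and 3, and 2 and 3 these were 21 and 7, 7 and 3, and 4 and 14. The cause of the differences between tools was not tested. The replicate block lowered the common dispersion from 0.334 to 0.0562.

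Lists called were 3, 2 and 7 in atrzf1 against WT, pca31 against atrzf1 and pca31 against WT. An estimated correlation gave 0, 0 and 0 and fry 0, 0 and 0, both with and without the block. Without regard to direction fry with the block called 2 lists in atrzf1 against WT, root markers (adjusted p = 0.043) and floral genes (0.0455), and 0 without it. Library totals gave 4, 4 and 7, the other scaling and filters 2 to 3, 2 to 3 and 6, and the replicate block 4, 3 and 5. The floral and morning clock lists had too few members left to test at 5 CPM. Leaving out 1 library gave 1 to 7, 2 to 7 and 3 to 8 lists. In atrzf1 against WT the number was 1 without atrzf1 library 1, 7 without WT library 3 and 5 without WT library 2 or atrzf1 library 2 or 3. In pca31 against atrzf1 it was 7 and 4 without atrzf1 libraries 2 and 3 and 6 without pca31 library 1 or 3, and in pca31 against WT 3 and 4 without pca31 libraries 2 and 3. The added fits with the block gave 2, 4 and 4 for numbers 1 and 2, 8, 7 and 9 for numbers 1 and 3, and 4, 6 and 10 for numbers 2 and 3, and numbers 1 and 2 without the block gave 2, 4 and 4. For the lists too the cause was not tested.

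Of the values of single genes under alternatives, 418 kept their side of the threshold, 64 passed it only under the alternative, 8 no longer passed, and 0 reversed. With 3 libraries per genotype and no block, simulated counts showed that genes changed 4-fold were not recovered (0 of 100), so a gene without a call is not shown to be unchanged. Counts of 0 allow up to 0.0867 to 0.131 CPM per library.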

Other observations

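Of the tests in this part, those on root markers, scaling, FT and SOC1, a deletion and reads on another gene were chosen after the result was seen, and those on anther markers and on other splits of the samples were written before. The genes in this paragraph were chosen after their values were seen, and 0 of them passed edgeR's test of all 9 libraries over all genes, with or without the block. The fits that did call them, named at the end of the paragraph, were added after the data were seen. SWEET10, a sugar transporter gene, was at 10.7, 11.8 and 9.55 CPM in atrzf1 libraries 1, 2 and 3, at 8.98, 12.8 and 4.89 CPM in pca31 and at 0.533, 3.32 and 1.49 CPM in WT (edgeR with the replicate block, adjusted p = 0.0578 and 0.0871). MAF5, a relative of FLC, was at 5, 2.37 and 0.109 CPM in atrzf1, 5.22, 1.82 and 0.199 CPM in pca31 and 13.6, 13.3 and 1.77 CPM in WT (0.123 and 0.0821 by the same edgeR test). QQS, a starch regulator gene, was at 2.54, 4.78 and 2.33 CPM in atrzf1, 4.41, 3.35 and 0.731 CPM in pca31 and 15.5, 25.7 and 5.07 CPM in WT. AT4G31480, a coatomer subunit gene, was at 134, 131 and 137 CPM in pca31, 67.8, 40.7 and 69.8 CPM in atrzf1 and 74, 50 and 62 CPM in WT, and its near copy AT4G31490 averaged 25.6, 29.1 and 26.3 CPM. MRD1, which overlaps HEI10 on the other strand so that their counts cannot be separated here, was at 99.5, 50.7 and 5.55 CPM in pca31, 0.981, 5.13 and 0.583 CPM in atrzf1 and 1.67, 23.2 and 0.275 CPM in WT. DESeq2 with the replicate block called SWEET10, MAF5 and QQS in atrzf1 against WT (adjusted p = 2.56e-08, 6.21e-05 and 0.00019), all 3, AT4G31480 and MRD1 in pca31 against WT (4.61e-06, 1.67e-05, 3.62e-07, 2.19e-06 and 0.0495), and AT4G31480 in pca31 against atrzf1 (6.08e-07). Limma-voom with the replicate block called QQS in both mutants against WT (adjusted p = 0.0253 and 0.0118), AT4G31480 in pca31 against atrzf1 and WT (0.0479 and 0.0193) and MAF5 in pca31 against WT (0.0216). Blocked edgeR fits to a pair of numbers called QQS with 1 and 2 (adjusted p = 0.0209 in atrzf1 and 0.0199 in pca31) and, in pca31, QQS with 2 and 3 (0.0148) and MRD1 with 1 and 3 (0.0384).

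Root markers were higher in the 3 number 3 libraries of all genotypes. Lower depth of these libraries is excluded as the cause, since it can only lower raw counts, and the raw counts of the list were at least 5.39 times those of the other libraries of the same genotype. Root tissue in the number 3 libraries, and little in the others, is a candidate explanation. Of 18 detected root genes outside the lists, 15 were also higher in number 3 in all 3 genotypes. By chance order 3.7% is expected for 1 gene, and the genes are not independent. PHT1;1, EXPA7, COBL9 and LRX1 of the root list reached at most 0.307 CPM in numbers 1 and 2. How seedlings were harvested stays open, because the labels describe all 9 libraries alike, although the number 3 libraries carry no number in the headings of the deposited counts. The pattern follows replicate number, so no explanation by genotype was tested. The test of root tissue, chosen after the result was seen, met its bound with 15 of 18 genes.

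Floral transcripts were higher in both mutants under numbers 1 and 2. Scaling is excluded as the cause, since the lowest median of the floral list under the other scalings was 1.49. Anther transcripts were present in mutant libraries 1 and 2, so flower buds with anthers are a candidate there. The anther markers A9 and LTP12 had 178 and 177 counts in atrzf1 library 1 and 123 and 190 in library 2. In pca31 they had 144 and 169 counts, and 233 and 200. Both had 0 in every number 3 library, while PKSA, PKSB, TKPR1 and AGP6 had counts in all libraries. Against WT, 10 of 16 detected anther and pollen markers were higher in both mutants under both numbers. This share lies between the bounds set beforehand, so anthers cannot be told apart from other sources of the difference from WT. By chance order 11.1% is expected for 1 gene, and the genes are not independent. WT library 2 held anther transcripts too, with A9 at 93 counts against 0 in WT library 1. Summed markers were 11.6, 25.6 and 11.1 CPM in WT libraries 1, 2 and 3. They were 64.5, 37.5 and 13.6 CPM in atrzf1 and 42.3, 53.5 and 14.9 CPM in pca31. Whether transcripts of GRP16, GRP14, EXL4, CYP96A15, XTH3, AT5G37940, GGPS2 and AT3G28500 come from flower buds was not tested. Earlier flowering through FT and SOC1 stays open too, with 9 of 12 comparisons higher (SOC1 5 of 6, FT 4 of 6). These counts include number 3. FT lay below WT in both mutants under number 1 and above it in both under number 2, while SOC1 lay above WT in both mutants under both numbers. The flowering repressor FLC, not part of this test, lay below WT in both mutants under every number. The genotypes remain an open biological explanation, as does a difference in age or harvest between libraries.

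AT4G21620 was low but above the floor in all 3 pca31 libraries, with 25, 42 and 38 counts. A deletion reaching the nearest genes with a mean of 1 CPM or more is excluded, since the lower of their fold changes was 0.04 on the log2 scale, although a smaller one between 11490423 and 11501162 stays open. AT4G21640 in this interval was at 0.509 CPM in pca31 and 0.258 CPM in atrzf1. Reads placed on AT4G21650 are excluded, as it gained 1.54 CPM against 327 CPM lost. It was the 1 annotated gene aligning over 100 bases or more at 90% identity or more. Annotated genes aligning less closely were not examined, and the unannotated copy was not counted in the files. AT4G21630, just past the gene on the minus strand (11492248 to 11495538), did not pass the expression filter. Reads moved onto it in all 3 pca31 libraries would have made it pass. A loss of most transcription, a change at the 3' end that moves reads off the gene, or a local lesion in pca31 could each give this value, and genomic reads across the gene would separate them.

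Other splits of the libraries were counted. The 6 libraries of 2 genotypes allow 10 splits, or 4 that exchange libraries within replicate numbers, too few for a share under 0.05. The 0 genes of atrzf1 against WT are reached by any split, here 10 of 10. Real and highest other numbers of genes were 0 and 0 in atrzf1 against WT, 1 and 0 in pca31 against atrzf1, and 1 and 0 in pca31 against WT, and of lists 3 and 12, 2 and 14, and 7 and 11. As many lists came from 8, 10 and 6 of the splits. Among the 4 splits that part all 3 pairs, as the real one does, the highest other numbers of lists were 4, 4 and 6, and splits that keep a number together gave 2 to 12, 3 to 14 and 4 to 11. With the replicate block the real and highest other numbers of genes were 7 and 7, 1 and 0, and 9 and 10, and of lists 4 and 6, 3 and 6, and 5 and 9. The blocked split with as many genes or more exchanged the number 3 libraries in each of the contrasts with WT. Of the 7 and 9 genes there, 5 and 6 have 0 counts in every number 3 library, so that exchange leaves their data as they were and says nothing about chance.

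Over all 9 libraries, 10 of 100 splits gave at least the 1 gene of the real one, and the highest gave 4966, so chance is not excluded by the count alone. The 3 splits that put the number 3 libraries together gave 4125 to 4966 genes, and 3 of the other 97 also gave over 10, at most 961. Counts so far above the real one point to a structure of the samples. A count of 0 is reached by any split, so the 100 of 100 splits with at least the 0 genes in opposite and in the same direction say nothing about chance (highest values 852 and 4045). With the replicate block 5 of 36 splits gave as many as 8 genes among genotypes (highest other 17), and 12 of 36 as many as 6 in the same direction (highest other 9). Of these splits 4 and 12 keep WT libraries 1 and 2 together. As 5 of the 8 and 5 of the 6 genes have 0 counts in every number 3 library, many splits differ little for them, and neither share says anything about chance.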
